A study of Mus musculus with 3 samples.

How the data were processed

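The data are 3 microarray samples of 1 group, ureters of wild-type FVB/N mouse embryos at embryonic day 15. Per the labels' protocols, ureters were dissected between the renal pelvis and the bladder, frozen in liquid nitrogen and extracted as total RNA with a column kit, and the RNA went through 2 rounds of amplification before biotin labelling and hybridisation to 1-colour Affymetrix Mouse Genome 430 2.0 arrays. Amplification of this kind starts at the 3′ end of transcripts, so probe sets far from it can stay dim for an expressed gene. The labels state that samples were not pooled. They do not say whether the 3 samples came from separate embryos or litters, so the spread between them may in part be technical, and they name no batch.

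The deposited values are linear intensities, 1 signal per probe set and array, and GCOS, the array maker's software, is named in the submitters' processing notes without version, algorithm or settings. All values were above 0, and the 2% trimmed mean was the same on the 3 arrays (1500 after rounding, from 1500.0081 to 1500.0087), so each array had been scaled to a common mean. No quantile normalization between arrays had been applied, since the medians differed (234, 198 and 273 in replicates 3, 8 and 9). Background handling, probe weights and detection calls are not given in the sources used here. Scaling to a common mean makes each level relative to the rest of its array, so that a sample with a larger share of 1 tissue's RNA has lower values for all others.

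Probe sets were named through the platform annotation, and symbols were compared by Entrez ID with the mouse reference gene table of assembly GRCm38.p6, which changed none of them and from which no coordinates were used. Of 45101 probe sets, 34958 had 1 gene symbol (34754 matched by Entrez ID), 932 had several and 9211 are not named here. Only probe sets with 1 symbol were used, giving 18194 genes. Probe sets that name several adult globin genes were therefore not used here, so that Hba-a1 rests on 1 probe set and Hbb-b1 was not analysed here, nor were some other list members without a probe set of their own. Signals were analysed as log2(signal + 1), and a gene was represented by its probe set with the highest mean log2 value over the 3 arrays. A gene with more probe sets thus had more chances to be above background. Of 6914 genes above background with several probe sets, 4968 (71.9%) had at least 1 probe set that was not above background.

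Without a second group or detection calls, background was measured from a reference list of 60 genes of tissues outside the dissection (retina, testis, lens, mammary gland, exocrine pancreas, stomach, pituitary, islet, thyroid and cerebellum), 55 of them measured. A gene was above background when its value exceeded the 95th percentile of that list on each of the 3 arrays. The share of each of 28 fixed lists above background was compared with that of all other named genes, the reference list left out, by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Agreement between samples was measured by Pearson's r and Spearman's rho across genes above background. For each list with at least 4 genes above background, the mean deviation from the 3-sample mean in each sample, after taking off the array's median deviation, was set against 10000 random lists of the same size matched on mean log2 value in 20 bins. A list stood apart in the outermost 0.05% of random lists at either end.

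The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 4 genes per list with the highest mean among those above background, members not above background, the 10 genes with the highest mean and the 10 with the largest range, the members of lists that stood apart, and the sex-linked genes and the control probe sets. Genes named outside it are said to have been singled out after their values were seen.

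Alternatives were quantile normalization, pseudocounts of 16 and 64, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, the 90th and 99th percentile of the reference list, presence on at least 2 arrays, leaving out each replicate, no filter on low values, no centring, and the median over a list's genes. An alternative without the 7 measured exocrine pancreas genes of the reference list was added after seeing the data, because some of them had its brightest probe sets.

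Both list tests were tested on simulated data. Among lists of 12 genes drawn from the 10694 genes above background, 0% of 100 unshifted lists were called high, 40% of 40 lists raised by 0.5 (log2) in 1 sample, and 97.5% of 40 lists raised by 1. Noise was drawn for each gene separately, so lists whose genes vary together were not simulated. The share test was run on 100 simulated families of 28 lists of 14 genes. With every list drawn at random it called 0.143% of lists. With 6 lists raised it called 29% of those with 13 genes above background and 100% of those with 14, and with 1 list raised 0% and 100%, so a list at 13 of 14 is often missed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.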

Results

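Gene expression was measured in the developing ureter, the muscular tube that carries urine from the kidney to the bladder, of wild-type FVB/N mouse embryos at embryonic day 15 (Theiler stage 23). The samples form 1 group of 3, named replicates 3, 8 and 9, each hybridised to a 1-colour Affymetrix Mouse Genome 430 2.0 array after 2 rounds of RNA amplification. The series profiles this tissue at 1 stage and holds no second group. The questions answered were therefore which cell types and pathways gave signal above background in the ureter, and how far the 3 samples differed. The arrays carried 45101 probe sets, and the median signal was 234 in replicate 3, 198 in replicate 8 and 273 in replicate 9. The number of arrays limits the precision of every level. Brightness also differs between probe sets for reasons other than transcript abundance, so the genes named by signal are those with bright probe sets, and their order does not rank transcripts.

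Of 18194 named genes, 10694 (58.8%) were above background on all 3 arrays. Background was set from 55 genes of tissues outside the dissection, such as retina, testis, lens and exocrine pancreas, and lay at a signal of 235 in replicate 3, 297 in replicate 8 and 344 in replicate 9. Cela1, a pancreatic elastase gene, was the 1 gene of this reference list above background, at 751 ± 104 (SD, n = 3). Each fixed gene list was compared with all other named genes by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over 28 lists). In 6 lists more genes were above background than elsewhere on the array, in 1 list fewer, and 21 lists did not pass the threshold. Without adjustment, 11 lists had p below 0.05. The test compares genes, which are not independent replicates.

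Transcripts of the urothelium, the epithelium lining the ureter, were above background for 8 of 13 measured genes, against 58.9% of other genes (adjusted exact p = 1). The transcription factor genes Foxa1 and Gata3 had mean signals of 5301 ± 1781 and 2277 ± 414 (SD, n = 3, as for all levels given as mean ± SD). The uroplakin genes Upk3b and Upk1b, which encode membrane proteins of the urothelial plaque, had signals of 1921 ± 699 and 1766 ± 804. Upk3b is also a member of the mesothelial list, so its signal need not come from the urothelium. The other uroplakin genes were not above background on all arrays: Upk1a had a signal of 269 ± 131, Upk3a 251 ± 229 and Upk2 99 ± 49. Pparg (440 ± 161) and Snx31 (266 ± 57) were not above background either. Of 14 general epithelial genes, 12 were above background (adjusted exact p = 0.11), among them the keratin genes Krt8 (20576 ± 3054), Krt18 (5937 ± 1390) and Krt19 (4986 ± 1414) and the adhesion gene Epcam (4436 ± 3354). The tight junction genes Cldn3 (305 ± 107) and Cldn4 (262 ± 106) were not. Without replicate 3 the epithelial list passed the test (adjusted exact p = 0.0412).

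Smooth muscle genes were above background for 12 of 16 (adjusted exact p = 0.377). Acta2, which encodes smooth muscle actin, had a signal of 31713 ± 3969, although only 1 of its 3 probe sets was above background. That probe set ends in _s_at, and without probe sets ending in _x_at or _s_at 11 of 16 smooth muscle genes were above background. Mylk, the myosin light chain kinase gene, had a signal of 20497 ± 7494, the tropomyosin gene Tpm2 14940 ± 688 and Mrtfb, a coactivator of serum response factor, 13480 ± 2128. Actg2 (2877 ± 645), Tagln (1398 ± 694) and Myh11 (1244 ± 674), contractile genes singled out after their values were seen, were also above background. Myocd, which encodes the coactivator myocardin, was above background on 2 arrays (662 ± 408), and Cnn1 (283 ± 178), Lmod1 (220 ± 113) and Aoc3 (438 ± 395) on 1 array each.

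The genes of mesenchymal transcription factors were above background more often than other genes, 14 of 15 (adjusted exact p = 0.04). They included Nfia (25559 ± 12288), Tbx18, a T-box gene of the undifferentiated ureteric mesenchyme (11783 ± 7187), Id4 (8749 ± 3610) and Tshz2 (7777 ± 2094), and Foxf2 was the exception (347 ± 199). All 13 fibroblast and extracellular matrix genes were above background (adjusted exact p = 0.0171). The collagen genes Col3a1 and Col1a2 had signals of 55422 ± 8078 and 37465 ± 8743, the intermediate filament gene Vim 37981 ± 3033 and the matrix gene Postn 22789 ± 7659. The call for mesenchymal transcription factors ended with the mean of a gene's probe sets (adjusted exact p = 0.1775), with the 90th percentile of the reference list as background (0.095) and, in an alternative chosen after seeing the data, without exocrine pancreas genes in that list (0.0947).

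Signalling genes were mostly above background. The BMP list passed the test with 13 of 14 genes (adjusted exact p = 0.0461), including the signal transducer genes Smad4 (23865 ± 2360), Smad1 (19601 ± 2903) and Smad5 (10785 ± 1042) and the receptor gene Bmpr2 (17467 ± 1842), while the antagonist gene Grem1 was not above background (281 ± 205). Without replicate 9 this call ended (adjusted exact p = 0.0518), as it did in 4 other alternatives. The Hedgehog list had 11 of 12 genes above background (adjusted exact p = 0.0593) and passed without replicate 9 (0.0398). Its members included the receptor gene Ptch1 (14272 ± 4419), the co-receptor gene Gas1 (13356 ± 1864), Smo (10503 ± 1832) and the effector gene Gli2 (9345 ± 2620). The ligand gene Shh, singled out after its values were seen, had a signal of 1386 ± 690, and the antagonist gene Hhip was above background on 2 arrays (419 ± 221). The WNT list had 14 of 16 genes above background (adjusted exact p = 0.0593), with Ctnnb1, the gene of beta-catenin, at 49403 ± 8255, the secreted modulator gene Sfrp2 at 32484 ± 3983 and the receptor genes Fzd2 and Fzd7 at 18118 ± 2554 and 14726 ± 2945. The ligand genes Wnt9b (177 ± 118) and Wnt2b (153 ± 31) were below background on every array. In the retinoic acid list 10 of 13 genes were above background (adjusted exact p = 0.386), including the receptor gene Rarb (4147 ± 1068), Aldh1a2 and Aldh1a1, which encode enzymes of retinoic acid synthesis (3553 ± 524 and 3095 ± 2442), and the reductase gene Dhrs3 (2578 ± 245). Rara (163 ± 114), Cyp26a1 (261 ± 90) and Stra6 (72 ± 60) were not.

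Channels and receptors of contraction and pacemaking were above background for 6 of 12 genes (adjusted exact p = 0.69). The gap junction gene Gja1 had a signal of 22297 ± 3361, and the angiotensin receptor genes Agtr2 and Agtr1a 8222 ± 1446 and 1455 ± 373. The chloride channel gene Ano1 had a signal of 4274 ± 1689 from a probe set ending in _s_at, and its other probe set was not above background. Without probe sets ending in _x_at or _s_at, 5 of 12 genes of this list were above background. The pacemaker channel genes Hcn2 (78 ± 39) and Hcn3 (51 ± 20) and the muscarinic receptor gene Chrm3 (31 ± 19) were below background on every array. Among posterior Hox genes, which pattern the body axis, 7 of 13 were above background (adjusted exact p = 0.875). These included Hoxa9 (12278 ± 1810), Hoxd10 (6693 ± 1799), Hoxa10 (3076 ± 1515) and Hoxc10 (2180 ± 406), whereas Hoxa13 (173 ± 52), Hoxd11 (129 ± 26), Hoxb7 (35 ± 15) and Hoxd12 (13.5 ± 10.6) were below background on every array.

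Genes linked to human urinary tract malformation were above background more often than other genes, 19 of 21 (adjusted exact p = 0.0274). The guidance gene Slit2 had a signal of 8068 ± 2221, the nuclear receptor cofactor gene Nrip1 7577 ± 1308, the integrin gene Itga8 5914 ± 2363 and the chaperone gene Trap1 5121 ± 1510. Only 1 of the 6 Nrip1 probe sets and 1 of the 3 Slit2 probe sets were above background. Robo2, which encodes a receptor for Slit proteins, had a signal of 34 ± 21 and Hpse2 164 ± 51, both below background on every array. This call ended in 4 alternatives, the highest adjusted exact p being 0.117 with the 99th percentile of the reference list as background. All 13 proliferation genes were above background (adjusted exact p = 0.0171), with the nucleotide reductase gene Rrm2 at 42494 ± 4077, Pcna at 35952 ± 3779, Mki67 at 31765 ± 7252 and the topoisomerase gene Top2a at 28773 ± 2666. The calls for the proliferation and matrix lists held under every alternative run. Of 14 immediate early and heat shock genes, which can respond to tissue handling, 12 were above background (adjusted exact p = 0.11), including Egr1 (8364 ± 1905), Jun (5313 ± 674), Hspa1b (4363 ± 1583) and Ier2 (4259 ± 252). Fosb (135 ± 29) and Junb (51 ± 25) were not.

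**Figure D1:**
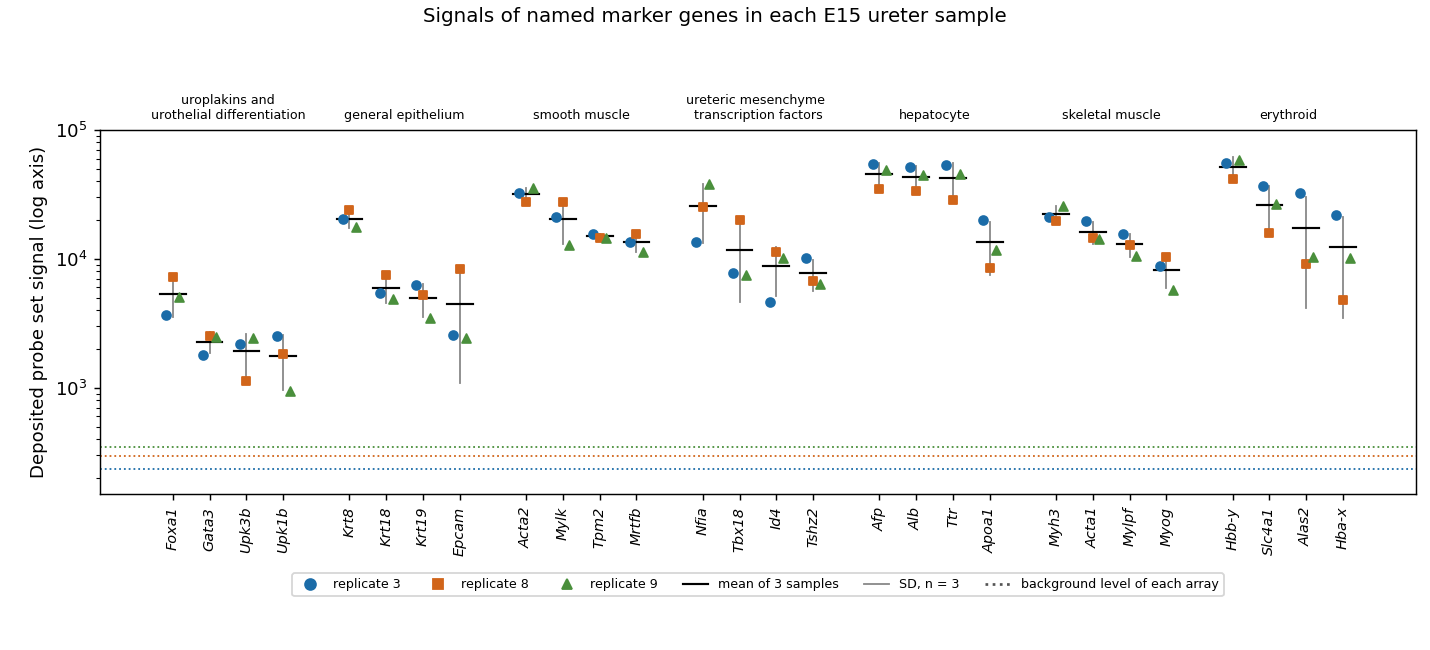
Signal (log scale) of genes named by the fixed rule in the 3 E15 ureter samples; points are single samples, black bars the mean, grey lines the SD (n = 3) and dotted lines the background of each array. Upk3b at a mean of 1921 and Tbx18 at a mean of 11783 lie above the background signals of 235, 297 and 344 on all 3 arrays.

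Lists of kidney cell types did not pass the test. With 7 measured genes, the renal stroma list was too short to pass above other genes even with all of them above background. That test therefore cannot show whether renal stroma genes were above background more often. Nephron progenitor genes were above background for 7 of 11 (adjusted exact p = 1), with Capn6 at 17942 ± 8082, the transcriptional coactivator gene Eya1 at 4920 ± 1933 and Crym at 2449 ± 802, while Cited1 had a signal of 174 ± 47. Nephron epithelium and podocyte genes were above background for 4 of 11 (adjusted exact p = 0.259): Hnf4a (5826 ± 2282, 1 of 4 probe sets), Podxl (4964 ± 1024), Synpo (2477 ± 558) and Wt1 (1842 ± 254). The nephrin gene Nphs1 (62 ± 39), the tubular transporter genes Slc34a1 (79 ± 22) and Slc12a1 (95 ± 39), the endocytic receptor genes Lrp2 (210 ± 73) and Cubn (213 ± 18), Umod (81 ± 43) and Fxyd2 (137 ± 34) were below background on every array. Ureteric tip and collecting duct genes were above background for 6 of 12 (adjusted exact p = 0.69), including Etv5 (2807 ± 1176), Calb1 (1681 ± 1319), Aqp3 (727 ± 312) and Emx2 (649 ± 176), whereas the water channel gene Aqp2 had a signal of 62 ± 54. Renal stroma genes were above background for 6 of 7 (adjusted exact p = 0.386), among them Foxd1 (11151 ± 1633), Penk (3522 ± 1258) and Alx1 (1874 ± 1819).

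Genes of other tissues were also above background. All 10 hepatocyte genes were (adjusted exact p = 0.04): Afp, the alpha-fetoprotein gene, had a signal of 45937 ± 9943, albumin (Alb) 43401 ± 9173, transthyretin (Ttr) 42763 ± 12997 and Apoa1, an apolipoprotein gene, 13432 ± 5915. Of 12 skeletal muscle genes 11 were above background (adjusted exact p = 0.0593), including the embryonic myosin gene Myh3 (22257 ± 3328), Acta1 (16253 ± 3118), Mylpf (12952 ± 2523) and the myogenic factor gene Myog (8273 ± 2289), with Myf5 the exception (166 ± 70). Erythroid genes were above background for 9 of 10 (adjusted exact p = 0.11), with the embryonic globin genes Hbb-y and Hba-x at 52093 ± 9105 and 12263 ± 8777, the erythrocyte anion exchanger gene Slc4a1 at 26362 ± 10237 and the haem synthesis gene Alas2 at 17251 ± 13093. The exception was the adult globin gene Hba-a1, whose 1 probe set used had a signal of 46 ± 33. Endothelial genes were above background for 10 of 13 (adjusted exact p = 0.386), including Tek (2929 ± 1308), Cdh5 (2275 ± 700), Sox18 (2180 ± 609) and Cldn5 (1967 ± 213), but not Pecam1 (236 ± 80). Macrophage and leukocyte genes were above background for 9 of 12 (adjusted exact p = 0.533), including the receptor gene Csf1r (10284 ± 6468), Mrc1 (3711 ± 1072), Lyz2 (3069 ± 1037) and Adgre1 (1679 ± 542).

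In the neuron and glia list 8 of 11 genes were above background (adjusted exact p = 0.69), with Stmn2 at 4621 ± 2820, Erbb3 at 3918 ± 593, Fabp7 at 2006 ± 1193 and Elavl4 at 1624 ± 177, while the neural crest gene Sox10 (382 ± 222) was above background on 2 arrays. Mesothelial genes were above background for 5 of 8 (adjusted exact p = 1), 4 of them shared with other lists (Podxl, Krt19, Wt1 and Upk3b), and Msln, the mesothelin gene, had a signal of 162 ± 109. Cartilage and bone genes were above background for 2 of 9 (adjusted exact p = 0.0961), Col9a1 (5624 ± 1685) and Hapln1 (1359 ± 550), whereas Col2a1 (288 ± 105) and Acan (333 ± 202) were not. Gonad and adrenal genes were above background less often than other genes, 2 of 11 (adjusted exact p = 0.0461): the steroidogenic genes Hsd3b1 (947 ± 452) and Star (833 ± 578). That call ended without replicate 8 (adjusted exact p = 0.0951), without replicate 9 (0.0959) and in 4 other alternatives. The call for the hepatocyte list ended in 3 alternatives, with adjusted exact p up to 0.095, although all 10 of its genes remained above background in each.

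**Figure D2:**
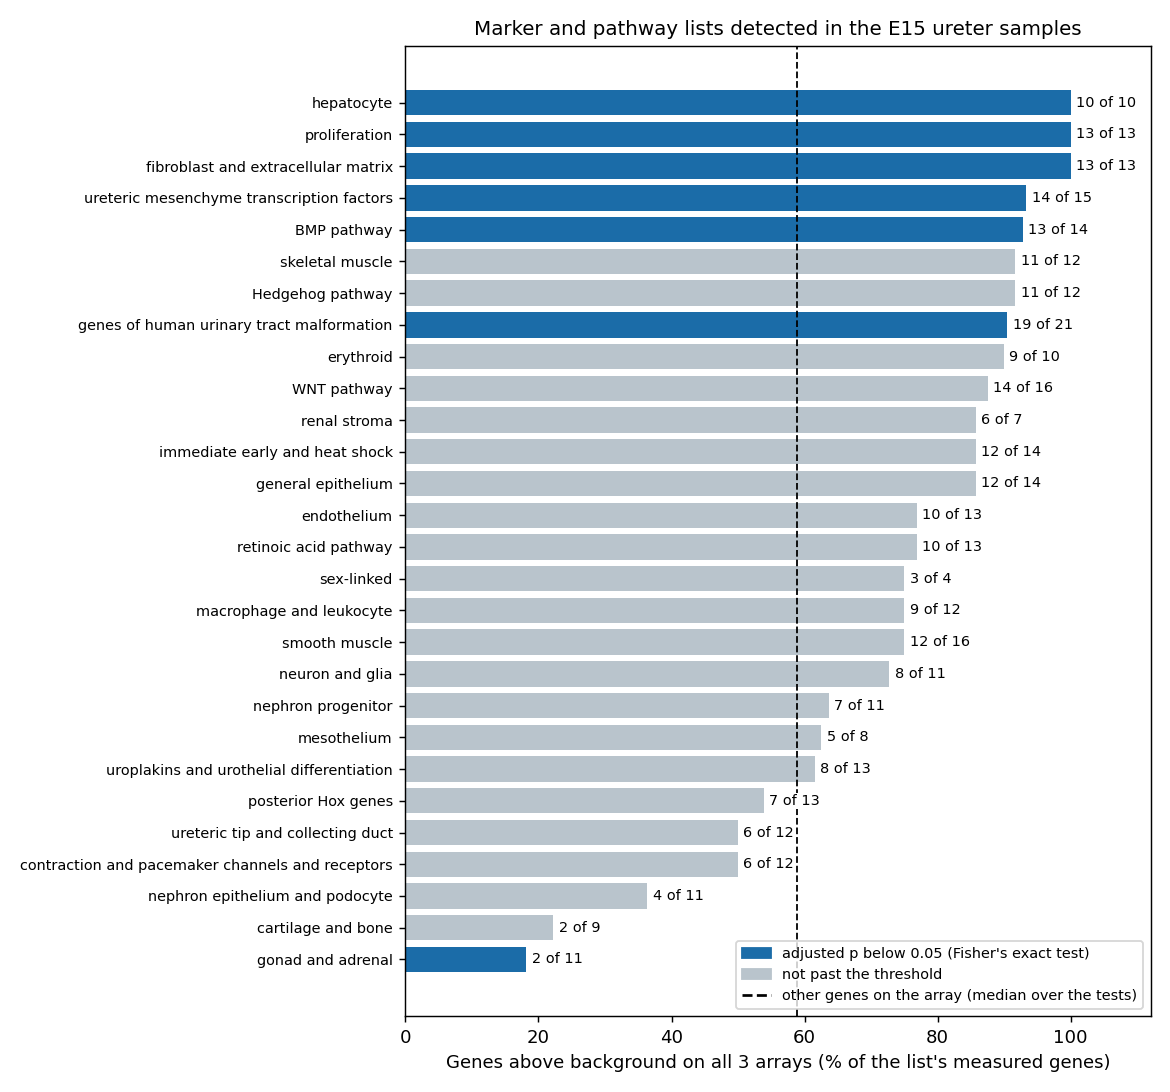
Share of each fixed list's measured genes (percent) above background on all 3 arrays, with counts beside the bars, blue bars for lists past the threshold of Fisher's exact test and a dashed line at the share of other genes, 58.9%. All 13 matrix genes, all 13 proliferation genes and all 10 hepatocyte genes were above background, against 2 of 11 gonad and adrenal genes.

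The sex of the embryos was given as unknown. Of 4 sex-linked genes measured, 3 were above background (adjusted exact p = 0.757). The Y-linked gene Eif2s3y had signals of 4868 in replicate 3, 3862 in replicate 8 and 3010 in replicate 9, and the Y-linked gene Kdm5d 986, 795 and 791. Uty was above background on 2 arrays (389 ± 163). Xist, the noncoding RNA that silences an X chromosome in females, gave signals of 1085, 1197 and 2093 with its brightest probe set, whereas another probe set gave 188, 7.69 and 868 and the last of its 3 was below background on every array.

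The 10 genes with the brightest probe sets, which need not be those with the most transcript, were Akr1a1, Hmgn1, the ribosomal protein gene Rpl13a, the chaperone gene Hspa8, Fabp5, the histone gene H2az1, Uqcrb, Serbp1, Eif4h and Fth1, the ferritin heavy chain gene. The mean signal of Akr1a1 was 63604 ± 9977 and that of Fth1 56165 ± 11030.

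The 3 samples were compared over the 10694 genes above background. Across genes, which are not independent replicates, Pearson's r between log2 signals was 0.949 for replicates 3 and 8 (Spearman's rho 0.948), 0.947 for replicates 8 and 9 (0.945) and 0.936 for replicates 3 and 9 (0.931). The median SD over the 3 samples was 0.29 on the log2 scale, and 1686 genes (15.8%) had a range of at least 1. The largest range was that of Nfix, a nuclear factor I gene, with signals of 817, 2546 and 21104 in replicates 3, 8 and 9 (range 4.69). It was followed by the teneurin gene Tenm2 (4.13), the GABA receptor gene Gabrb1 (3.98), Taf15 (3.94), Prap1 (3.64), Alx1 (3.62), the splicing factor gene Srrm2 (3.58), Sphkap (3.56), the methylcytosine dioxygenase gene Tet2 (3.55) and Gatad2b (3.31). These ranges are those of single probe sets. Of these genes, 4 had another probe set above background, which in replicate 9 deviated in the same direction for Nfix (2.60 against 2.61) and Gatad2b (0.85 against 2.18) and in the opposite one for Srrm2 (−0.53 against 1.85) and Tet2 (−0.53 against 2.19). By the probe sets used, all of these genes but Alx1 were highest in replicate 9, whereas Alx1 was highest in replicate 8 (signals of 313, 3871 and 1438). Over all 1686 genes, 612 were highest in replicate 3, 490 in replicate 8 and 584 in replicate 9.

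Control probe sets at the 3′ and 5′ ends of the same transcript, which show how far labelled RNA reached from the 3′ end, differed between samples. The ratio of 3′ to 5′ signal of Gapdh was 18.9 in replicate 3, 15.1 in replicate 8 and 16.4 in replicate 9, and that of Actb 7.45, 6.5 and 4. For pyruvate carboxylase it was 10.5, 5.95 and 2.65, and for the transferrin receptor 7.67, 9.57 and 7.21. The 3′ signal of 18S ribosomal RNA was 13767, 17568 and 49634. These values come from single arrays and have no replicate error.

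Cell type lists differed between the samples, with hepatocyte and blood genes high in replicate 3 and low in replicate 8. The mean deviation of the 10 hepatocyte genes from the 3-sample mean was 0.79 (log2) in replicate 3, −0.67 in replicate 8 and −0.12 in replicate 9. All 10 were above their 3-sample mean in replicate 3 and none in replicate 8; Apob, the gene of apolipoprotein B, deviated by 1.33 in replicate 3 and −1.06 in replicate 8. Erythroid genes deviated by 0.63 in replicate 3 and −0.76 in replicate 8, including Epb42 (1.52 and −1.13), Alas2 (1.15 and −0.69) and Hba-x (1.10 and −1.11). Macrophage and leukocyte genes were low in replicate 8 (−0.61), including the complement gene C1qb (−0.97) and Csf1r (−0.82).

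The general epithelial, ureteric tip, mesenchymal transcription factor and BMP lists were high in replicate 8, whereas the urothelial list (−0.12) and the matrix list (−0.11) did not stand apart there. General epithelial genes deviated by 0.38 (10 of 12 above their 3-sample mean), led by the claudin gene Cldn7 (1.33), Epcam (1.14) and the E-cadherin gene Cdh1 (0.87). Ureteric tip and collecting duct genes deviated by 0.47 (5 of 6), led by Calb1 (1.22) and Etv5 (0.63). In replicate 9 the ureteric tip list deviated by −0.36 and the general epithelial list by −0.29, and neither stood apart there. Mesenchymal transcription factor genes deviated by 0.30 in replicate 8 (10 of 14 above their 3-sample mean) and −0.30 in replicate 3 (5 of 14), among them Tbx18 (0.91 and −0.44), Gata2 (0.80 and −0.90) and Tbx3 (0.72 and −0.97). Tshz2 (−0.20 and 0.42), Foxf1 (−0.31 and 0.16) and Gata6 (−0.15 and 0.04) went the other way. BMP genes deviated by 0.25 in replicate 8 (10 of 13) and −0.34 in replicate 3 (3 of 13), among them the decoy receptor gene Bambi (0.65 and −0.95) and the target gene Id1 (0.62 and −0.67), while the ligand gene Bmp4 deviated by 0.14 and −0.86. Neuron and glia genes were low in replicate 3 (−0.56, 2 of 8 above their 3-sample mean), including Stmn2 (−1.42), Th, the tyrosine hydroxylase gene (−1.01), and Fabp7 (−0.69). Elavl4 deviated by −0.11, S100b by 0.23 and Erbb3 by 0.08. In replicate 9 the neuron and glia list deviated by 0.51 (7 of 8 genes above their 3-sample mean) but did not stand apart (99.85th percentile).

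The values that stood apart were 12 of 75 list values, in 8 of 25 lists. They lay outside all but the most extreme of 10000 random lists of the same size and mean level (beyond the outermost 0.05% at either end), against 0.075 such values on average for random lists. Random lists were drawn gene by gene, so they lack the shared variation of genes of 1 cell type or pathway. A list's deviations are taken from its mean over the samples, so they offset each other and are not separate events. Each value describes 1 sample, so no p-value was computed. The hepatocyte, erythroid and macrophage values stood apart in 8 of 8 alternatives, the others in 4 to 7, and with the mean of a gene's probe sets 7 values did.

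**Figure D3:**
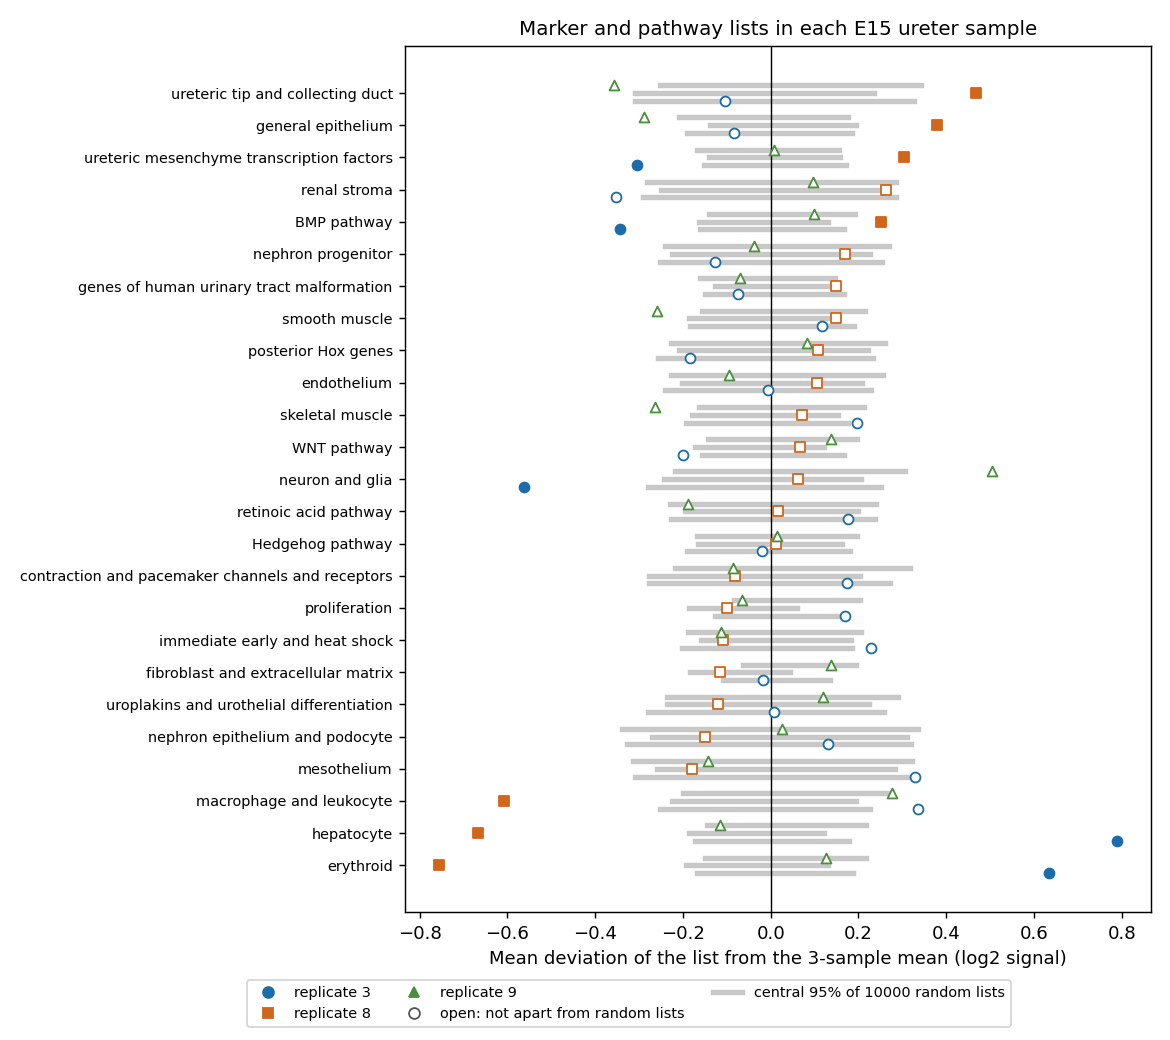
Mean deviation of each list's genes above background from the 3-sample mean (log2 signal) in each E15 ureter sample; filled points stood apart from 10000 random lists, open points did not, and grey bars hold the central 95% of the random lists. The hepatocyte list lies at 0.79 in replicate 3 and −0.67 in replicate 8.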

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

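The alternative without pancreas genes in the reference list was chosen after seeing the data. No paired analysis was possible because there is only 1 group. The count of genes above background ran from 8572 to 11506 over all alternatives (main value 10694), and the calls for the matrix and proliferation lists held in each. Other calls lay close to the threshold, and which list passed changed with where background was set. The values that follow are adjusted exact p of the share above background. With the mean of a gene's probe sets, calls ended for mesenchymal transcription factors (0.1775), BMP (0.1005) and gonad and adrenal genes (0.0607), immediate early genes passed (0.0373), and uncalled lists changed side for channels (1), Hox (0.843), neuron and glia (1) and sex-linked genes (0.798). With the 90th percentile as background, calls ended for mesenchymal transcription factors (0.095), BMP (0.0954), malformation (0.095), hepatocyte (0.095) and gonad and adrenal genes (0.0954), and Hox (0.838) and mesothelium (1) changed side. With the 99th percentile, BMP (0.0849) and malformation (0.117) calls ended, epithelium (0.0239), WNT (0.0119) and erythroid genes (0.034) passed above other genes, ureteric tip and collecting duct genes passed below them (0.0239), and urothelium (1) and neuron and glia (1) changed side. With presence on at least 2 arrays, malformation (0.05), hepatocyte (0.0683) and gonad and adrenal (0.196) calls ended, Hedgehog genes passed (0.0307) and Hox genes changed side (0.779). Without probe sets ending in _x_at or _s_at, Hedgehog (0.0465), WNT (0.0397) and skeletal muscle genes (0.0465) passed, and mesothelium (0.609) and sex-linked genes (1) changed side. Without pancreas genes in the reference list, calls ended for mesenchymal transcription factors (0.0947), BMP (0.1006), malformation (0.0579), hepatocyte (0.0947) and gonad and adrenal genes (0.1006), and Hox genes changed side (0.871). Leaving out each replicate gave 0.0412 to 0.201 for epithelium (passing without replicate 3), 0.0398 to 0.0951 for Hedgehog (passing without replicate 9), 0.0239 to 0.0518 for BMP (ending without replicate 9), 0.838 to 1 for Hox (changing side without replicate 9) and 0.0412 to 0.0959 for gonad and adrenal genes (ending without replicates 8 and 9). The lowest r between samples (0.936) was 0.923 with the mean of a gene's probe sets, 0.945 without a filter, and 0.938 to 0.952 with each replicate left out. The count of genes with a range of at least 1 (1686) was 6300 without a filter, where dim genes enter, and 751 to 971 (751 without replicate 3, 971 without replicate 8, 785 without replicate 9) with each replicate left out, where the range is taken over 2 samples. With the mean of a gene's probe sets, 7 list values stood apart in place of 12, and those of mesenchymal transcription factors (−0.34 in replicate 3, 0.14 in replicate 8), BMP in replicate 8 (0.20), ureteric tip in replicate 8 (0.18) and neuron and glia in replicate 3 (−0.58) no longer did. Without a filter, mesenchymal transcription factors (−0.29 and 0.25) and BMP (−0.31 and 0.15) in replicates 3 and 8 did not; with the median over genes, epithelium (0.26), BMP (0.21) and ureteric tip (0.41) in replicate 8 did not, nor did BMP there without _x_at and _s_at probe sets (0.23). In replicate 9, values that had not stood apart did so for smooth muscle without _x_at and _s_at probe sets (−0.31) and for neuron and glia without a filter (0.52). Apart from the filter and the smaller number of samples, the cause was not tested. Signal over background limits what can be said of dim genes: 1 gene of the reference list was itself above background, and a gene not above it may still be expressed.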

Other observations

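The test on other probe sets of genes highest in replicate 9 was chosen only after the result was seen, and that pattern was narrowed to genes highest in replicate 9 after a first run on all genes of large range. The gene lists used here were written after the report's lists had been seen and before their own values were.

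Several genes outside the report's lists were above background in all 3 ureter samples. Of 9 heart-muscle genes 6 were, including the cardiac actin gene Actc1 (39407 ± 6162, SD, n = 3, as below), Myh7 (8817 ± 2609) and Tnnt2 (6921 ± 2265), which developing skeletal muscle also uses, whereas the atrial genes Myl7 (256 ± 13) and Nppa (70 ± 57) were not. Of 9 noncoding RNAs of the nucleus 8 were, including the imprinted transcripts Meg3 (31007 ± 7979), Kcnq1ot1 (3130 ± 1495), Rian (2436 ± 476) and Airn (1106 ± 345). Of 7 skin genes 5 were, including the keratin gene Krt10 (7664 ± 1158) and Lor, the loricrin gene (3001 ± 2895). Of 7 gut genes 3 were, Fabp1 (10926 ± 4311), which liver also expresses, Fabp2 (1193 ± 251) and Lgals4 (610 ± 393). Of 7 forebrain genes 1 was (Bcl11b, 3218 ± 738), and of 5 lung genes none, Sftpc having a signal of 250 ± 61.

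Liver, skeletal muscle and embryonic blood transcripts were above background in all 3 ureter samples, with Alb at 43401 ± 9173, Myh3 at 22257 ± 3328 and Hbb-y at 52093 ± 9105. For RNA of the whole embryo as the source, fewer genes were above background than predicted. Of 26 forebrain, lung, gut and skin genes 9 (34.6%) were, 38.7 percentage points below a second liver list (Fisher's exact p = 0.0247). This rests on forebrain and lung (1 of 12), while gut and skin (8 of 14) lay near other genes. The lists were not matched on level in their own tissues. A small share of whole-embryo RNA is therefore not excluded, nor is RNA of single other tissues. Fetal liver RNA may have entered the samples, but 11 of 15 genes (73.3%) of the second liver list were above background, 1 gene short of the bound of 75% set beforehand, against 58.9% of other genes. RNA of skeletal muscle may have entered likewise, with 10 of 14 genes (71.4%) of a second muscle list above background. Neither share reaches its bound, and neither differed from that of other genes by Fisher's exact test (p = 0.304 and 0.423). A share counts genes without weighing their level, so it cannot decide. Both sources stay open, as does expression of these genes within the ureter itself. A floor raised for all genes would raise the background level too, and that level was 235, 297 and 344 in replicates 3, 8 and 9. The 11 second-list liver genes above it had mean signals of at least 3132, which argues against such a floor for these genes. The design has no group that tests a biological explanation.

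Liver and blood lists were high in replicate 3 and low in replicate 8. The tables argue against array scaling as the whole cause, since after quantile normalization the hepatocyte list still differed by 1.40 (log2, 1.46 before; random lists −0.24 to 0.30). In the ureter's own lists replicate 8 exceeded replicate 3 by 0.60 for mesenchymal transcription factors, 0.46 for epithelium and 0.03 for smooth muscle, and the difference was −0.10 for matrix and −0.13 for urothelium. A candidate explanation is a different share of fetal liver RNA: the second liver list was 1.62 higher in replicate 3 than in replicate 8 (random lists −0.29 to 0.26), and all 11 of its genes above background were above their 3-sample mean in replicate 3. In replicate 9 the second liver list deviated by −0.40, whereas the hepatocyte list (−0.12) and the erythroid list (0.13) lay within their random ranges, so whether blood follows liver stays open; no biological explanation was tested, as there is only 1 group.

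Genes with a range of at least 1 that were highest in replicate 9 included Nfix, whose other probe set above background moved alike there (2.60 against 2.61), and Tet2, whose other one moved the opposite way (−0.53 against 2.19). For 213 of them with another probe set above background, that probe set deviated in replicate 9 by a median of 0.397 of the named one (95% bootstrap interval 0.323 to 0.463), and in the same direction for 80.3%, against 56.1% of 3428 genes of smaller range. This lies between the bounds set for an effect on single probe sets (0.25) and on whole transcripts (0.5), so these cannot be told apart; probe sets chosen for a large range are also bound to exceed their neighbours. More nuclear RNA in replicate 9 may contribute, since nuclear noncoding RNAs deviated there by 0.35 (99.14th percentile of random lists, 7 of 8 genes higher). In that list, Kcnq1ot1 (range 1.57) and Miat (1.41) were themselves highest in replicate 9 with a range of at least 1. This support is therefore partly drawn from the genes to be explained. The list was also low in replicate 8 (−0.41), and Neat1 was lower in replicate 9 (516) than in the others (748 and 706). Rian (2549 against 2847) and Mirg (554 against 575) were lower in replicate 9 than in replicate 3, and Meg3 was nearly equal (36162 and 35042). Malat1, Kcnq1ot1, Miat and Airn were higher in replicate 9 than in replicate 3. The 3′ to 5′ ratios of Actb (4, against 7.45 and 6.5) and pyruvate carboxylase (2.65, against 10.5 and 5.95) were lowest and the 18S signal highest (49634, against 13767 and 17568) in replicate 9, while the Gapdh ratio (16.4) lay between the others; whether RNA quality accounts for these genes was not tested, nor was a biological explanation.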
